A study of Mus musculus with 3 samples.

How the data were processed

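Tables of 3 two-colour arrays on mouse four-cell embryos were analysed. Per the labels, total RNA from each pool of embryos was extracted with RNeasy Plus Micro columns, and 240 pg was amplified in successive rounds with the TrueLabeling-PicoAMP kit and coupled to CyDyes. HP pools were labelled with Cy5 and control pools with Cy3. Each of the 3 arrays (Agilent design with mm7 coordinates, 1 slide) held 45018 spots, of which 43379 were non-control spots for 41174 probes.

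Per the file headers, the scans were quantified with Agilent Feature Extraction 9.5.1.1. The deposited mean spot signals and median local background signals are intensity values of the scan with no background subtracted. The deposited processed signals are intensity values after background subtraction with spatial detrending and dye normalization within the array, in which dim values are replaced by surrogates. The deposited log ratio is the log10 of the Cy5 over the Cy3 processed signal. The authors' series table holds the same log10 values as the scanner tables, with a largest difference of 5e-10. Its median was 0 on each array, and 48.5%, 44.1% and 53.6% of its values were 0 on replicates 1, 2 and 3, where both channels held surrogates.

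The starting point here was the mean signal and the local background. Values were read with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), background-corrected with normexp (offset 50), and normalized within each array by loess with control spots at weight 0. Spots called non-uniform or population outliers by the scanner software were left out (208, 172 and 325 spots on replicates 1, 2 and 3), and spots of the same probe were averaged, including 245 probes with 10 spots. A probe was tested when it was well above background, by the scanner software's call, in the same channel on at least 2 of 3 arrays. That left 8590 probes. Symbols were updated to the RefSeq gene table of the mouse reference, by transcript accession for 23070 probes, by symbol for 6585 and by unique synonym for 3077. The name in the tables was kept for 8442. A gene was represented by the tested probe with the highest mean log2 intensity, which gave 7255 genes, 7246 of them with values on all 3 arrays. Of 1148 genes with several tested probes, 469 had a probe of opposite sign. No genome sequence was used, and positions are those of the array design.

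The comparison was HP against control within each array: an intercept fitted to log2 (Cy5 over Cy3) with limma and empirical Bayes moderation (prior degrees of freedom 2.08, beside 2 residual degrees of freedom), with Benjamini-Hochberg adjustment over probes or over genes and a threshold of 0.05. Dye and treatment run the same way on every array, so no dye term could be fitted. Standard errors are moderated. The fold count asked for a log2 ratio of at least 1, or at most −1, on all 3 arrays. Gene lists were tested with limma camera at a preset correlation of 0.01 for the 23 of 25 lists with at least 5 tested members, with the estimated correlation and fry as alternatives. Correlations between arrays are across genes and carry no p.

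The rule for named genes, the lists and the other settings were fixed before the data were examined. For each direction the rule takes up to 12 genes past the adjusted threshold, and otherwise the smallest p among genes with the same sign on all 3 arrays whose brighter channel was well above background on all 3. Names that are only clone or accession numbers were passed over (3 higher and 1 lower). The rule had 1416 higher and 1490 lower genes to choose from. For each list it takes the members with the smallest p, and it adds a set of reference genes. Some genes that the rule takes are not reported here. Other members named in the text were chosen after their values were seen.

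The other settings were the scanner software's processed log ratio, the series table, no background subtraction, an offset of 0, median centring in place of loess, scale normalization between arrays, no filter on dim probes, a filter on both channels of all arrays, array weights, trended and robust moderation, separate channels with no replicate block, the mean over probes of a gene, an estimated correlation, fry, a threshold of 0.1, a fold of 1.5, and leaving out each replicate. Removal of a trend on probe base composition, and counting replicates 2 and 3 as 1 replicate, were added after the data were seen. Removal of this trend also sets the mean log2 ratio of the tested probes of each array to 0.

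The steps were tested on simulated data with changes set in 100 genes per size among 7255. Arrays and genes were independent, and the spread was drawn from the fitted prior. Of genes set to a log2 change of 1, 1 of 100 passed adjustment and 89% had an unadjusted p under 0.05. Of genes set to 2, 67 of 100 passed and 95% were 2-fold on every array. Of 7055 genes set to no change 6 passed and 22 were 2-fold on every array. A simulated shift of −0.5 in the ribosomal list was found by camera in 50 of 50 simulations with the preset correlation and in 0 of 50 with the estimated correlation. In 1 of 50 simulations without a shift a list was called.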

Results

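Gene expression was measured in pools of mouse four-cell embryos. They came from oocytes held under high hydrostatic pressure (HP, 20 MPa for 60 min at 37 °C) or from control oocytes kept in the same conditions without pressure, and both were then fertilised, by injection of sperm into the oocyte per the sample labels and in vitro per the title of the series. There were 3 HP pools of 44, 30 and 37 embryos and 3 control pools of 36, 33 and 24 embryos. Each of 3 two-colour Agilent arrays held the HP pool and the control pool with the same replicate number. The HP pool carried Cy5 and the control pool Cy3 on every array, so an effect of the dye and an effect of pressure run in the same direction throughout. Of the non-control spots, 19.1%, 19.9% and 17.5% were well above background in the HP channel of replicates 1, 2 and 3, and 20.0%, 23.2% and 18.5% in the control channel. No spot was saturated. The number of arrays limits the precision, and the p-values measure only the spread between these 3 pairs of pools.

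The comparison asks which transcripts differ, by the four-cell stage, between embryos from pressure-treated and from control oocytes. Log2 ratios are HP over control, as mean ± standard error over n = 3 arrays. With loess the highest of the leading genes was Dcun1d1, which promotes attachment of the ubiquitin-like protein NEDD8 to cullins, at 2.03 ± 0.14 or 4.08-fold higher in HP. Prdx4, a peroxidase of the endoplasmic reticulum, followed at 1.83 ± 0.23, and Errfi1, an inhibitor of the epidermal growth factor receptor, at 1.61 ± 0.19. The lowest was Cenpe, a kinetochore motor protein of mitosis, at −2.63 ± 0.28 or 6.21-fold lower in HP. Tpr, a protein of the nuclear pore basket, was at −2.08 ± 0.19, and Lmna, which encodes the A-type lamins of the nuclear envelope, at −1.26 ± 0.13. Each of these genes had the same sign on all 3 arrays, but none passed adjustment over all genes (limma adjusted p = 0.174 for each). Their order and size depended on the scaling. With the scanner's own log ratios Errfi1 was at 3.48, Gemin8 at 3.47, Prdx4 at 2.96, Prkar2b at 2.94 and Dcun1d1 at 2.64, with Tpr at −3.23 below Cenpe at −3.02.

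The 24 leading genes were the 12 in each direction with the smallest p among named genes of 1 sign on all 3 arrays. On the higher side the deubiquitinase Usp4 was at 1.15 ± 0.13 and Fem1b, a substrate receptor of a cullin ubiquitin ligase, at 1.14 ± 0.14. A second probe of Usp4 gave 0.03, and a second probe of Fem1b gave −0.23. Prkar2b, a regulatory subunit of protein kinase A, was at 1.20 ± 0.15, and Ppp2r5c, a regulatory subunit of protein phosphatase 2A, at 0.83 ± 0.10. The others were Gemin8 (1.28 ± 0.12), part of the complex that assembles spliceosomal particles, Hpf1 (1.28 ± 0.16), a cofactor of ADP-ribosylation after DNA damage, the thiamine transporter Slc19a2 (1.24 ± 0.16), Ugdh (1.003 ± 0.111), which makes the precursor of hyaluronan, and the RNA helicase Dhx33 (0.91 ± 0.11). The second probe of Prdx4 gave −0.18, so the value of this gene rests on a single probe. With median centring these higher genes ran from 0.02 for Dhx33 to 1.28 for Dcun1d1, with Fem1b at 0.10, Ppp2r5c at 0.23, Hpf1 at 0.27, Ugdh at 0.36 and Usp4 at 0.51, against a median of −0.39 over all tested genes.

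On the lower side Pcnt, a scaffold of the centrosome, was at −0.97 ± 0.10. Both probes of Tpr were low, at −2.08 and −1.27, while a second probe of Lmna gave −0.14. Psmb3, a subunit of the proteasome core, was at −1.37 ± 0.14, Rpl22 of the large ribosomal subunit at −1.21 ± 0.13, Ndufc2 of respiratory complex I at −1.06 ± 0.11 and Wdr46, a nucleolar protein of ribosome assembly, at −1.33 ± 0.12. The remaining 4 were Smpdl3a, a phosphodiesterase related to acid sphingomyelinase (−1.35 ± 0.14), Gulo, the final enzyme of vitamin C synthesis (−1.12 ± 0.11), Emc10 of the endoplasmic reticulum membrane complex (−1.11 ± 0.12), and M6pr, a receptor that sorts lysosomal enzymes (−1.02 ± 0.11). The other probes of M6pr gave −0.56 and 0.26. With median centring these lower genes ran from −3.50 for Cenpe to −1.65 for Emc10 and Pcnt, with Tpr at −2.79, Psmb3 at −2.23, Lmna at −2.15, Wdr46 at −2.13, Rpl22 at −1.95, Gulo at −1.86 and M6pr at −1.83. The probe of Dcun1d1 (A_52_P414420) lies on chromosome 3 at 35700242 to 35700301 and that of Cenpe (A_51_P164014) on chromosome 3 at 135067767 to 135067826. The probe of Prdx4 (A_52_P313861) lies on chromosome X at 150138058 to 150138117. These are mouse mm7 coordinates of the array design.

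**Figure D1:**
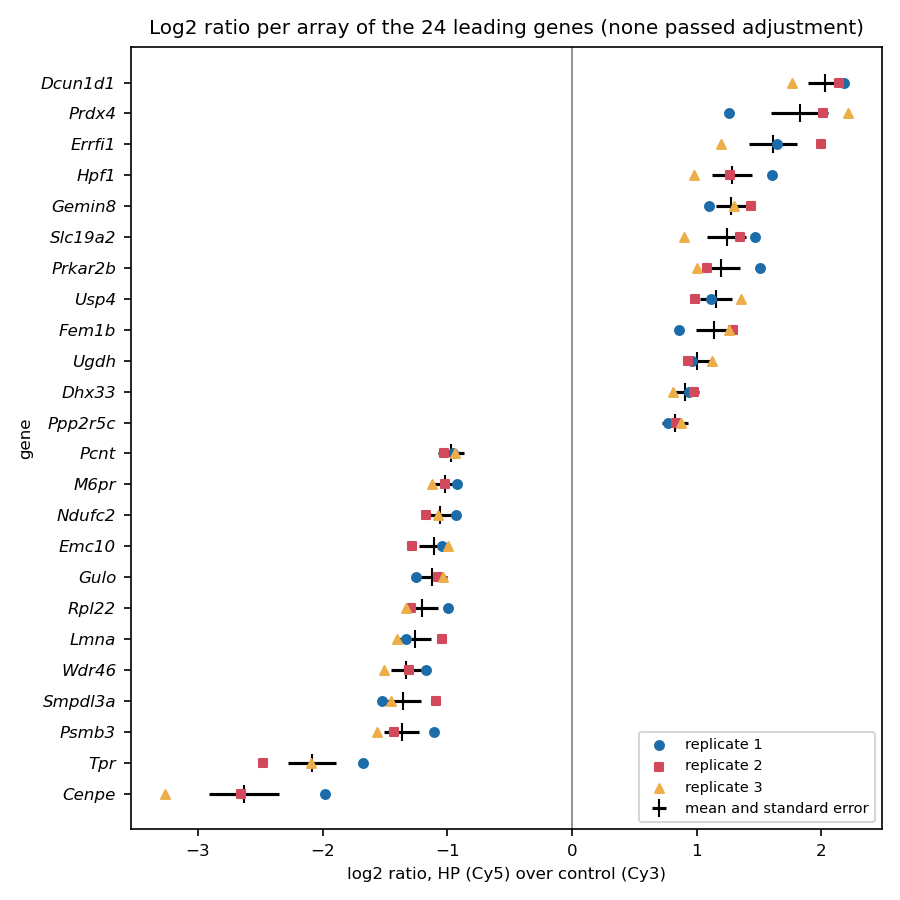
Log2 ratio of HP over control (horizontal axis) of the 24 leading genes (vertical axis). Symbols give the 3 arrays, and bars the mean and standard error. All 3 values of each gene lie on the same side of 0, from Cenpe at −2.63 to Dcun1d1 at 2.03.

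Of 7255 genes tested with limma, 0 passed an adjusted p of 0.05, with a lowest adjusted p of 0.174, and of 8590 probes 0 passed, with a lowest of 0.177. At an unadjusted p under 0.05 there were 1342 genes, 526 higher and 816 lower in HP, against 362.75 expected from independent arrays with no difference. For probes the count was 1528, with 602 higher and 926 lower. All 3 arrays had the same sign for 3497 genes or 48.3%, against 25% expected from independent signs. Replicates 2 and 3 correlated at r = 0.65 across genes, which these expected values do not allow for. A change of at least 2-fold on every array was seen for 30 probes, 11 higher and 19 lower, among them Dcun1d1, Prdx4, Errfi1, Cenpe and both probes of Tpr. Counted by the brightest probe of each gene, 27 genes met this rule, as did 22 of 7055 genes simulated with no change. The simulated arrays were independent, with a spread drawn from the fitted prior. Turning replicate 1, 2 or 3 of the real data gave 7, 0 and 0 such probes. So the simulated count is not a measured chance level. Median centring sets the median of all non-control spots of an array, most of them dim, to 0 and leaves a trend with intensity. With median centring in place of loess, the median of the tested genes moved to −0.39, and 1047 genes passed, 5 higher and 1042 lower, 16 of the 24 leading genes among them. At an unadjusted p under 0.05 there were then 47 higher and 2547 lower genes, and 1 higher and 377 lower probes were 2-fold on every array. With the trend on probe base composition removed, 644 genes were higher and 698 lower at an unadjusted p under 0.05. That step also sets the mean of the tested probes of each array to 0, and the 2 effects were not separated. So the excess of lower genes depends on the scaling. Without replicate 1, 2 or 3 the count at an unadjusted p under 0.05 was 1799, 702 or 751 genes, and the count of probes 2-fold on every array left was 269, 55 or 92.

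Among 25 gene lists fixed before the data were examined, the ribosomal proteins of the cytosol had the lowest mean. Of 77 measured members, 71 were lower in HP and 57 were lower on all 3 arrays, with a mean log2 ratio of −0.51 (−0.32, −0.55 and −0.68 on replicates 1, 2 and 3). Rpl22 was at −1.21 ± 0.13 and Rpl35 at −0.99 ± 0.12, while Rpl21 at 0.56 was the highest of the 6 members above 0. The translation factors, which start, extend and end protein chains, were lower too. Of their 28 members 21 were lower, 15 of them on all 3 arrays, with a mean of −0.28. Eef1g, a subunit of the elongation factor complex, was at −0.86 ± 0.11 and Eif4ebp1, a repressor of cap-dependent translation, at −0.69 ± 0.12. A second probe of Eef1g gave 0.33.

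The mitochondrial respiratory chain list was also lower, with 48 of 62 members lower in HP, 31 of them on all 3 arrays, and a mean of −0.33 (−0.10, −0.47 and −0.41). Ndufc2 and Ndufa13, both of complex I, were at −1.06 ± 0.11 and −0.85 ± 0.13, and Cox5a at 0.49 was the highest member. The maternal oocyte transcripts stood on the other side. Of 25 members 20 were higher in HP, 12 of them on all 3 arrays, with a mean of 0.27 (0.13, 0.34 and 0.35). Oog1, an oocyte-specific gene that is prominent at the time of zygotic genome activation, was at 1.48 ± 0.20 (0.27 with median centring). Btg4, an adaptor for the decay of maternal mRNA, was at 0.68, Oosp1, an oocyte-secreted protein, at 1.29, and Gdf9, an oocyte growth factor, at 0.97. Khdc3, a member of the subcortical maternal complex, went the other way at −1.30 ± 0.24. With median centring, which moved the median of all tested genes to −0.39, the mean of the maternal list was −0.21, and those of the ribosomal, respiratory and translation lists were −1.36, −1.02 and −1.07. With the scanner's own log ratios the mean of the maternal list was 0.69.

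These 4 of the 23 lists with at least 5 members passed the competitive test of limma camera with a preset correlation of 0.01. The adjusted p was 4.54e-14 for ribosomal proteins, 0.000287 for the respiratory chain, 0.00699 for maternal transcripts and 0.0234 for translation factors. The correlation estimated from the 3 arrays was 0.203, 0.171, 0.00829 and −0.0199 in this order. For the ribosomal and respiratory lists it lay far above the preset, so their p-values may be too small. None of the 4 held when the correlation between genes was estimated from the 3 arrays, with adjusted p = 0.651 with an estimated correlation for each. That test found a simulated shift of −0.5 in the ribosomal list in 0 of 50 simulations, so its failure cannot decide. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction, gave an adjusted p of 0.117, 0.147, 0.117 and 0.00317 in the same order. No member passed over all genes. Adjusted over the list alone, 39 ribosomal, 9 respiratory, 6 maternal (Oog1, Khdc3, Btg4, Oosp1, Fbxw19 and Oas1c) and 1 translation factor gene (Eef1g) passed. Here and below, this adjustment does not allow for the number of lists. Of all 7255 genes, 1342 had an unadjusted limma p under 0.05. The maternal and translation calls were lost with a filter that asked for signal in both channels on all arrays (adjusted p = 0.0686 and 0.0600). The translation call was also lost without replicate 1 (0.0514) and without the intensity offset (0.0520). Over 18 other settings all 4 lists kept their direction relative to the other genes. Several of these settings could not change it. An estimated correlation, fry, array weights and separate channels leave this value as it was, and the series table repeats the scanner's log ratios. The adjusted p ran up to 0.651 for each list, from 2.96e-25 for ribosomal proteins, 3.04e-06 for the respiratory chain, 0.00256 for maternal transcripts and 3.65e-05 for translation factors.

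**Figure D2:**
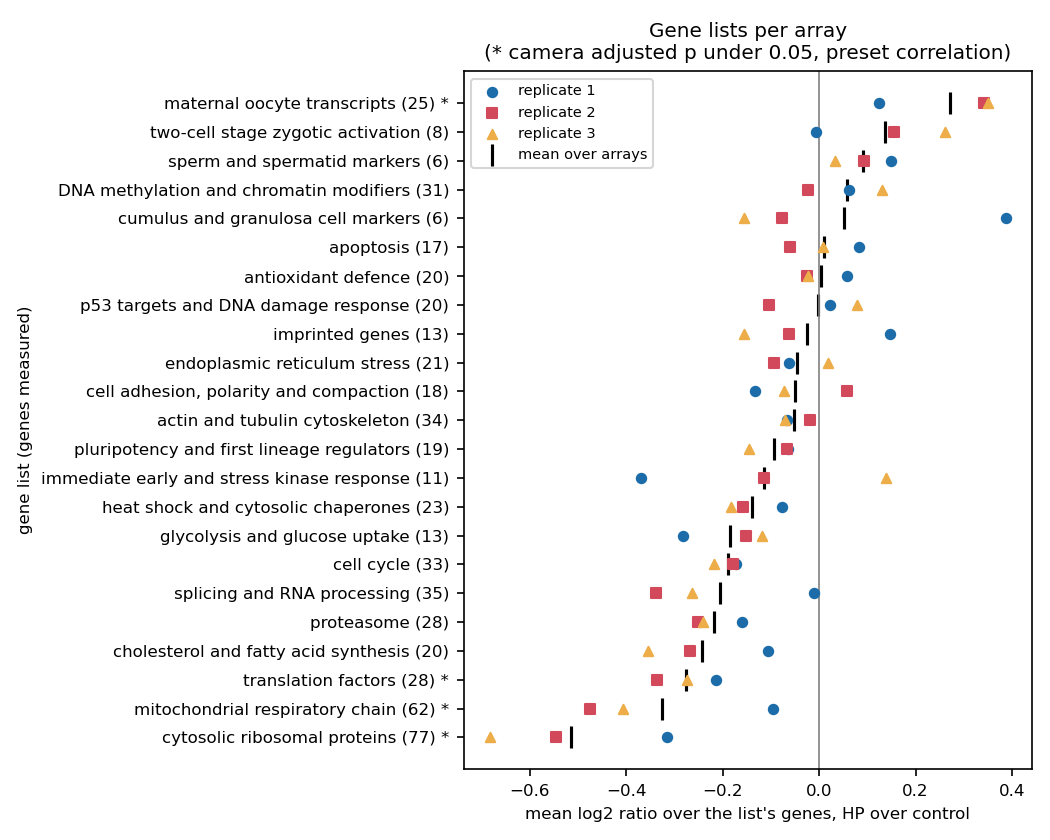
Mean log2 ratio of HP over control (horizontal axis) of each gene list with at least 5 measured members, the number in brackets (vertical axis). Symbols give the 3 arrays and bars their mean, from −0.51 for ribosomal proteins to 0.27 for maternal transcripts (−0.21 with median centring).

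Replicates 2 and 3 shared more than either shared with replicate 1. Across 7246 genes, which are not independent replicates, the log2 ratios of replicates 2 and 3 correlated at r = 0.65 (rho 0.64), against 0.23 (0.27) for replicates 1 and 2 and 0.22 (0.24) for replicates 1 and 3. The HP pools of replicates 2 and 3 were much closer to each other than any other pair of the 6 pools. The SD over genes of their difference in log2 signal was 0.231, against 0.463 to 0.642 for the other pairs, and 0.179% of genes lay at least 2-fold apart. For the pairs of control pools the SD was 0.465, 0.523 and 0.496. The labels give 30 and 37 embryos for these HP pools, and they were kept as separate replicates. With replicates 2 and 3 averaged and counted as 1 replicate, a choice made after seeing the data, limma again passed 0 genes, 865 had an unadjusted p under 0.05, and the same 4 lists passed camera with the preset correlation, of which none held over the 3 arrays with an estimated correlation (adjusted p = 0.651). The mean of the ribosomal list was then −0.46 and that of the respiratory list −0.27. The test with an estimated correlation found 0 of 50 simulated ribosomal shifts, so its failure cannot decide.

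**Figure D3:**
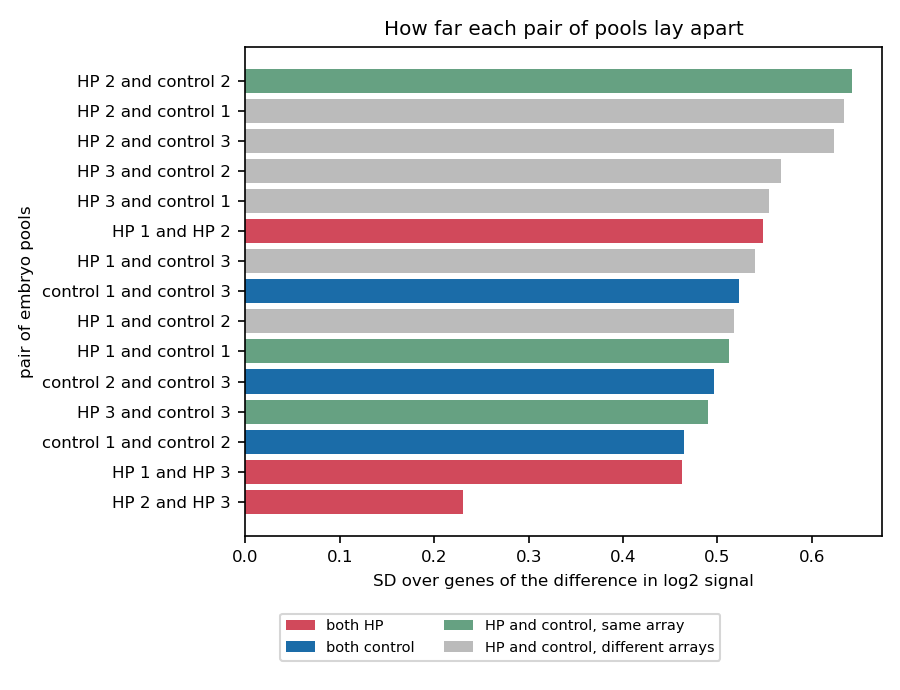
SD over 7246 genes of the difference in log2 signal (horizontal axis, from 0) for each pair of the 6 embryo pools (vertical axis), with colours for the kind of pair. The bar of HP pools 2 and 3 ends at 0.231, and all others end between 0.463 and 0.642.

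Lists of other housekeeping functions had means below 0 that did not pass. The splicing list of 35 genes had a mean of −0.20 (camera adjusted p = 0.1004), with Lsm7 at −0.48 and Sf3b4 at −0.77, both components of spliceosomal particles. It passed with median centring (0.00256), with scale normalization between arrays (0.0372), with array weights (0.0446), without the filter on dim probes (0.00739) and without replicate 1, but its adjusted p was 0.651 with an estimated correlation, as it was for the cholesterol, proteasome and cell cycle lists. The test with an estimated correlation also found 0 of 50 simulated ribosomal shifts, so its failure cannot decide. Cholesterol and fatty acid synthesis had a mean of −0.24 over 20 genes, 17 of them lower (0.104), and of −0.74 with the scanner's own log ratios, where the splicing mean was −0.36. Dhcr7, the final enzyme of cholesterol synthesis, was at −0.36. The sterol carrier Stard4 was at −0.87, with an HP signal that was not well above background on any array. The proteasome list had a mean of −0.22 over 28 genes (0.202) and held members on both sides, with Psmb3 at −1.37 and the activator subunit Psme2 at 0.80. Adjusted over the list alone 4 proteasome genes passed. Glycolysis had a mean of −0.18 over 13 genes (0.340), with 11 lower. Hk1, which phosphorylates glucose, was at −0.96 (second probe 0.05). Ldhb, a lactate dehydrogenase subunit, was at 0.87 (−0.06 with median centring) and passed when adjusted over the list alone. Cell cycle genes had a mean of −0.19 over 33 genes (0.432), 21 of them lower. Cenpe passed when adjusted over the list alone, and the replication helicase subunit Mcm7 was at −0.67. With median centring the cell cycle and proteasome lists passed (0.000244 and 0.0238), and without the filter the cholesterol list did (0.0211).

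The stress lists did not pass camera, which tests a common shift and cannot show members that move both ways. The mixed form of fry, which allows both directions, gave p-values not adjusted over lists. They ran from 0.00724 for p53 targets to 0.546 for immediate early genes. With median centring, where the median of all tested genes was −0.39, their means lay between −0.68 and −0.52, against −0.14 to 0.01 with loess. Heat shock proteins and cytosolic chaperones had a mean of −0.14 over 23 genes, 17 of them lower (camera adjusted p = 0.551), and a mean of −0.43 with the scanner's own log ratios. Dnajb1, a heat-inducible co-chaperone, was at 0.56 (−0.32 with median centring) and Cacybp at −0.49. The inducible chaperone Hspa1a was at −0.66 ± 0.53, with 0.60, −1.95 and −0.64 on the 3 arrays, and another of its probes gave 0.01. The signal of the first probe was well above background on 1 HP array and 2 control arrays, which limits this ratio. The constitutive Hspa8 was at −0.02, from a dim probe (mean log2 intensity 6.66), which limits this ratio. The array design places this probe on chromosome 5 at 5787852 to 5787911. Probe sequences were not realigned, so whether it measures Hspa8 was not tested. Endoplasmic reticulum stress genes had a mean of −0.05 over 21 genes (0.803), with the chaperone Hyou1 at −0.88 and the co-chaperone Dnajb9 at 0.73 (−0.37 with median centring, and −0.00 for another of its probes). Antioxidant defence had a mean of 0.00 and a median of −0.07 over 20 genes, with a camera direction of down (0.873). There Prdx4, at 1.83, passed when adjusted over the list alone. The mitochondrial thioredoxin Txn2 was at −0.53, and the superoxide dismutases Sod1 and Sod2 were at −0.01 and −0.16. p53 targets and DNA damage genes had a mean of −0.00, a median of −0.11 and a camera direction of up (0.937). Sesn1, a p53-induced regulator of growth signalling, was at 1.22 and the repair protein Brca2 at −0.65 (0.46 and −1.59 with median centring). Apoptosis genes had a mean of 0.01, a median of −0.01 and a camera direction of up (0.937), with the inhibitors Birc5 at 0.44 (−0.66 with median centring) and Birc6 at −0.42. Immediate early and stress kinase genes had a mean of −0.11 over 11 genes (0.658) that differed between arrays (−0.37, −0.11 and 0.14). In this list Myc was at −0.72 (−0.17, −1.29 and −0.69 on the 3 arrays) and Btg1 at −0.28. Relative to the other tested genes this list was at −0.08, and at 0.28 with the scanner's own log ratios.

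Lists of embryonic programmes did not pass camera either. Their p in the mixed form of fry, not adjusted over lists, ran from 0.000114 for two-cell genes to 0.337 for adhesion genes. Genes of zygotic activation at the two-cell stage had a mean of 0.14 over 8 genes, 5 of them higher (camera adjusted p = 0.551), of 0.59 with the scanner's own log ratios and of −0.52 with median centring, where it lay at −0.02 relative to the other genes. Adjusted over the list alone 3 passed: Tcstv3, a gene of the two-cell burst, at 0.71 (0.20 with median centring), Usp17la at 0.56 and Sp110 at −0.82 (−1.93 with median centring). Pluripotency and first lineage regulators had a mean of −0.09 over 19 genes (0.803), with Klf4 at −0.52 and Gata6, a regulator of primitive endoderm, at −0.85. DNA methylation and chromatin modifiers had a mean of 0.06 over 31 genes (0.582), and of −0.50 with median centring. Uhrf1, which guides maintenance DNA methylation, was at 1.31 ± 0.27 (0.715 with median centring), and Cbx3, a heterochromatin protein, at 0.37 (−0.68 with median centring). Imprinted genes had a mean of −0.02, a median of 0.12 and a camera direction of up over 13 genes (0.798). Phlda2, a maternally expressed regulator of placental growth, passed when adjusted over the list alone at 0.80 (−0.07 with median centring), and Igf2r was at −1.15. Cytoskeleton genes had a mean of −0.05 over 34 genes (0.803), with Actr3, which nucleates branched actin, at 0.91 (−0.18 with median centring), Myl12b at −0.60 (second probe 0.08) and Actb at −0.12. The Actb probe was dim (mean log2 intensity 6.56), with an HP signal well above background on 2 arrays. Cell adhesion, polarity and compaction genes had a mean of −0.05 over 18 genes (0.803). Pou5f1, Nanog, Cdx2, Cdkn1a and Xist were too dim to test, and no probe carried the symbol Gapdh or Hspa1b.

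Markers of cells other than the embryo were mostly dim. Cumulus and granulosa markers had 6 measured genes with a mean of 0.05 (camera adjusted p = 0.582), at 0.39, −0.08 and −0.16 on the 3 arrays. Nr5a1, a steroidogenic regulator, was at 0.24 (−0.28 with median centring) and Inhbb, an inhibin subunit, at 0.48, with 1.13, 0.44 and −0.14 on the 3 arrays (0.10 with median centring). Sperm and spermatid markers had 6 measured genes with a mean of 0.09 (0.513), of 0.37 with the scanner's own log ratios and of −0.21 with median centring, with the testis kinase Tssk1 at 0.24 (−0.04 with median centring) and the acrosomal protease Acr at 0.16 (−0.11 with median centring). Blood and immune markers had 2 measured genes, too few to test, with Hba-a1 at 0.10 and C1qb at 0.05 (−0.01 and −0.06 with median centring). Of the sex-linked transcripts 3 were measured, also too few. Uba1y was at −0.89 and Kdm5d at −0.23, both with an HP signal not well above background on any array, and Eif2s3y was at 0.14.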

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

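Tests on signal brightness, on the part of each list's gap that the base composition trend carried, on the shared signal of replicates 2 and 3 (dye, common RNA), on slower development, and on splits of the arrays, except the split for gene lists, were chosen only after the result was seen. The groups hold 3 arrays, too few for a test of single arrays that stand apart.

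Spike-in control probes, which the comparisons do not use, gave a median signal above the 95th percentile of the negative controls in 3 array channels. The medians were 48.064 against 47.0 in the HP channel and 52.8989 against 52.1 in the control channel of replicate 1, and 50.7901 against 49.2 in the HP channel of replicate 2. In the other 3 channels the spike-in median was below that percentile.

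In the test with a preset correlation ribosomal, respiratory and translation genes were lower and maternal transcripts higher in HP, but none of the 4 calls held with an estimated correlation (adjusted p = 0.651 for each), and with median centring the maternal mean was −0.21, which is 0.289 above the other genes there. The test with an estimated correlation found a simulated ribosomal shift of −0.5 in 0 of 50 simulations, so its failure cannot decide. Loess removes the trend with intensity that median centring leaves. After loess the ribosomal, respiratory, translation and maternal lists lay apart from the other genes by −0.487, −0.295, −0.243 and 0.306. They passed there with the preset correlation. These 4 lists were singled out by this same result, so it cannot decide whether a trend with brightness is the whole cause. Removal of the trend on probe base composition also set the mean of the tested genes of each array to 0. The means of the lists were then −0.477 (SD over arrays 0.171), −0.294 (0.203), −0.236 (0.0625) and 0.308 (0.119). Of their gaps to the other genes, which this centring leaves alone, that trend carried −0.00440 (SD 0.0254), 0.00128 (0.0168), −0.00619 (0.00957) and −0.00347 (0.00310). This argues against base composition as the whole cause. For the respiratory list it rests on the gap alone, a test chosen after the result was seen. The mean of that list did not clear the bound set beforehand by more than its SD. Slower development of the HP pools may leave more maternal RNA, but the two-cell stage list, at 0.137 with an SD of 0.135, leaves this undecided. An effect of pressure on the oocyte, or of the dye on single transcripts, stays open and untested, because each HP pool carried Cy5.

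More genes had an unadjusted p under 0.05, and a common sign on all arrays, than 3 independent arrays with no difference would give, though replicates 2 and 3 were not independent in this sense (r = 0.65), and with them averaged as 1 replicate 865 genes had such a p. Log2 ratios of 2 probes at separate places of the same gene correlated at r = 0.318 over 1021 genes (95% interval 0.25 to 0.383), against −0.0154 for random pairs matched on intensity. A bias of single probe sequences would give no such relation and so is not the whole cause. A dye effect shared by all probes of a transcript could still give it, and with no array of swapped dyes it cannot be separated from an effect of pressure.

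The samples allow 4 splits that turn whole arrays and so keep each HP pool paired with its control pool. The other splits of the 6 pools would break pairs and were not used. The 4 splits are too few for a share under 0.05. For genes at an unadjusted p under 0.05 the real split gave 1342 and the highest other 483, and 1 of 4 splits gave as many. For probes the values were 1528 and 573, with 1 of 4 as large. For probes 2-fold on every array they were 30 and 7, again 1 of 4, and for gene lists 4 and 3, also 1 of 4. For probes and for genes past adjustment with limma all 4 splits gave 0. Where the splits differed, the highest other value came from the split that turned replicate 1 and so kept replicates 2 and 3 together.

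Replicates 2 and 3 shared more of their log2 ratios than either shared with replicate 1. A dye effect of equal size on every array would give equal covariances, but that of replicates 2 and 3 exceeded the mean of the others by 0.139 (95% interval over genes 0.127 to 0.151), which argues against it as the whole cause. This excess restates the likeness already seen, and the interval takes genes as independent and leaves out the spread between arrays. Local artefacts on the slide are argued against too, since the correlation was 0.650 after the median of each block of the spot grid was removed. A common RNA or amplification behind both HP channels could bring their SD to 0.231, but spots within an array leave out the spread between arrays and give no measure to set it against. Such a common origin and a stronger likeness of these embryo pools cannot be told apart, since no array repeats a single pool, and a dye effect that differs in size between arrays was not tested.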

How the results depend on the processing

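The settings with probe base composition removed and with replicates 2 and 3 as 1 replicate were chosen after seeing the data, and all others before. The 24 leading genes kept their sign in all 382 values, which 15 or 16 of the 21 other settings gave for each gene. Their choice by 1 sign on all 3 arrays fixed this where a replicate was left out or replicates 2 and 3 were averaged. It also fixed this with array weights and with scale normalization. The filter settings reuse the same log2 ratios of each probe. Trended moderation and separate channels leave the mean log2 ratio unchanged, and the series table repeats the scanner's log ratios. With median centring alone 16 of the 24 leading genes passed limma adjustment, while Dhx33 was at 0.02, Fem1b at 0.10, Ppp2r5c at 0.23, Hpf1 at 0.27 and Ugdh at 0.36. Over all 74 named genes 1157 of 1175 values kept the sign. Probes and genes past adjustment stayed at 0 in each other setting run but median centring, with fold and correlation results having no value where a setting does not enter them. The ribosomal, respiratory, maternal and translation lists kept their direction in 18 of 18 settings and passed in 16, 16, 15 and 14. An estimated correlation, fry, array weights and separate channels could not change these directions. Most probes were dim, and a ratio near background is limited by it. Values of lists below are means relative to the other tested genes, and where no reason is given the cause was not tested.

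Median centring centres each array on all non-control spots, most of them dim. Bright spots were dimmer in the HP channels, with 99th percentiles of 1401, 1444 and 1095 against 2321, 3352 and 2190 in the control channels. Bright genes therefore lie lower with this scaling. With median centring the median of all tested genes was −0.39, and the counts rose to 1140 probes and 1047 genes past adjustment, 2978 probes and 2594 genes at an unadjusted p under 0.05, 378 probes 2-fold on every array and 7 lists. The cell cycle (−0.4419), proteasome (−0.2981) and splicing (−0.3879) lists then passed. The sign turned for antioxidant (−0.0214), p53 (−0.0634), apoptosis (−0.0638), two-cell (−0.0216), chromatin (−0.0055), cytoskeleton (0.0115) and adhesion (0.0365) lists. It turned for Dnajb1 (−0.3159), Dnajb9 (−0.3656), Birc5 (−0.6635), Ldhb (−0.0603), Cbx3 (−0.6759), Phlda2 (−0.0651), Actr3 (−0.1842), Nr5a1 (−0.2815), Tssk1 (−0.0352), Acr (−0.1073), Hba-a1 (−0.0066) and C1qb (−0.0606).

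With the scanner's processed log ratio, and with the series table of the same values, 547 probes were 2-fold on every array and the immediate early list was at 0.2753. Without background subtraction 72 probes were 2-fold. With an offset of 0 there were 111, the translation list at −0.2707 no longer passed and Sod1 was at 0.0284. With scale normalization 15 probes were 2-fold, splicing passed (−0.2113), and endoplasmic reticulum stress (0.0056) and imprinted genes (−0.0375) turned. Without the filter on dim probes, which tests more probes, 2585 had an unadjusted p under 0.05, cholesterol (−0.1521) and splicing (−0.1669) passed and imprinted genes were at −0.0141. With the filter on both channels, which tests fewer genes, 2 lists passed. Maternal (0.3263) and translation (−0.2625) did not, and p53 (−0.0238), imprinted (−0.0251), cytoskeleton (0.0389) and adhesion (0.0446) turned. Array weights brought splicing (−0.173) past the threshold. With an estimated correlation 0 lists passed, with maternal at 0.3057, ribosomal at −0.487, respiratory at −0.2954 and translation at −0.2434. This setting also found 0 of 50 simulated ribosomal shifts. With fry 1 list passed, and maternal (0.3057), ribosomal (−0.487) and respiratory (−0.2954) did not. A fold of 1.5 was met by 262 probes, by its construction.

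Without 1 replicate, which leaves 2 arrays, between 55 and 269 probes were 2-fold on every array, 798 to 2131 probes and 702 to 1799 genes had an unadjusted p under 0.05, and the correlation between arrays was 0.2226 to 0.6526, highest without replicate 1. Values ran from −0.2065 to 0.0399 for immediate early genes, −0.0822 to 0.0771 for imprinted genes, −0.0675 to 0.0197 for adhesion, −0.0888 to 0.1911 for cumulus markers, −0.2754 to −0.1024 for splicing, −0.279 to −0.2091 for translation factors, −0.0426 to 0.0142 for endoplasmic reticulum stress, −0.0064 to 0.0858 for p53 targets, −0.0537 to 0.0045 for Hspa8 and −0.1484 to 0.1075 for Sod1. Splicing passed, and translation factors failed, without replicate 1. With base composition removed, which also re-centres each array, Hspa8 was at 0.0763. With replicates 2 and 3 as 1 replicate, which leaves fewer degrees of freedom, 974 probes and 865 genes had an unadjusted p under 0.05 and Sod1 was at 0.0656.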

Other observations

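Families of genes by the stem of their symbol were tested only after the other results were seen, with limma camera over 61 families, of which 4 passed with the preset correlation and none with an estimated correlation (adjusted p = 0.794 for each of the 4). The test with an estimated correlation found 0 of 50 simulated shifts of the ribosomal list, so its failure cannot decide. The stems Rpl (43 genes) and Rps (37 genes) stand mostly for large and small subunit proteins of the cytosolic ribosome, and so largely repeat the ribosomal list. A stem takes in any symbol that starts with it and a digit, so it can hold genes that are not ribosomal proteins. The 2 stems were at −0.58 and −0.36, at −1.36 and −1.15 with median centring, and at −0.84 and −0.51 with the scanner's own log ratios. Mitochondrial ribosomal proteins of the large subunit (Mrpl), which translate the mitochondrial genome, were lower as well: 30 of 34 were lower in HP, 16 of them on all 3 arrays, with a mean of −0.30 (adjusted p = 0.009996, and −0.06, −0.42 and −0.43 on replicates 1, 2 and 3). This mean was −0.95 with median centring and −0.48 with the scanner's own log ratios. Mrpl33 was at −0.92, Mrpl39 at −0.88 and Mrpl23 at −0.73. Those of the small subunit (Mrps) had a mean of −0.25 over 20 genes and did not pass (0.0962). Olfactory receptor genes (Olfr) were higher: 21 of 23 were higher in HP, 17 on all 3 arrays, with a mean of 0.19 (adjusted p = 0.0298) that was −0.13 with median centring, where it stayed above the other genes by 0.37, and 0.68 with the scanner's own log ratios. Olfr1134 was at 0.75 and Olfr609 at 0.74. These receptors were dim, at a mean brightness percentile of 34.4. By chromosome, 0 of 20 tests passed, with a lowest adjusted p of 0.910.

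Beside the leading genes, other probes were at least 2-fold apart on every array and were named after their values were seen. Counted by the brightest probe of each gene, 27 genes met this rule, as did 22 of 7055 genes simulated with no change. The brightest probes of Psmc6 and Rab11fip1 did not meet it, at −1.46 and −0.88. The simulated arrays were independent, and turning 1 array of the real data left at most 7 probes that met the rule. So the simulated count is not a measured chance level. On the higher side were Kdm1b, a histone demethylase of growing oocytes needed for maternal imprints, at 1.82 ± 0.26, Pias2, a SUMO ligase, at 1.66 ± 0.36, Tmem9b at 1.53 ± 0.22 and Plekha3, a phosphoinositide-binding protein of the Golgi, at 1.34 ± 0.18. On the lower side were Snhg5, a host gene of small nucleolar RNAs, at −1.95 ± 0.22, Dgka, a diacylglycerol kinase, at −1.63 ± 0.22, Mast1 at −1.61 ± 0.23, Psmc6, an ATPase of the proteasome cap, at −1.60 ± 0.21, Chic1 at −1.59 ± 0.18 (its HP signal was not well above background on any array, which limits this ratio), Hmgxb4 at −1.45 ± 0.16, Ago2, the small RNA slicer, at −1.38 ± 0.17, Rnf130 at −1.18 ± 0.14 and Rab11fip1 at −1.13 ± 0.12. Other probes gave 0.24 for Chic1 and −0.24 and −0.02 for Ago2. The size of these values depended on the scaling. With median centring Kdm1b was at 0.88, Pias2 at 0.87 and Plekha3 at 0.55, and the lower probes named here ran from −2.69 for Snhg5 to −1.86 for Rnf130. With the scanner's own log ratios Tmem9b was at 2.94, Pias2 at 2.28, Snhg5 at −2.68, Dgka at −3.04, Ago2 at −2.41 and Chic1 at −6.01. With loess none of them passed adjustment over probes with limma.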
